A study of Mus musculus with 4 samples.

How the data were processed

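Poly(A)-selected RNA was sequenced in paired-end mode from 4 mouse samples, per the labels' protocols. Of these, 2 were hippocampi of F1m-CON and F1m-GCS offspring, and 2 were cultures of HT22 cells, CON and SUP. Each group held 1 library. Hippocampus samples were assigned by their source names and HT22 samples by the choline concentration in their titles.

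Per the series' design text, the authors trimmed reads with Trim Galore, aligned them with TopHat2 to the mouse mm10 build, counted them with HTSeq and compared groups with edgeR. CASAVA 1.8 is also named, without its role, per the submitters' processing notes. Versions other than that of CASAVA are not given in the sources used here. Per the series' design text, up to 2 mismatches and a mapping quality of at least 4 were allowed. The deposited tables, 1 per comparison, list the same 22328 genes, 21932 of them protein coding, with coordinates. Among the protein-coding genes 99.8% of the lengths were multiples of 3, so the lengths are called coding lengths here. The 13 mitochondrial genes were listed at 0 reads, in all 4 libraries, so mitochondrial reads could not be used as a measure of RNA quality.

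The count columns are the authors' raw read counts per gene, per the file headers. The RPKM columns are the authors' values per kilobase of coding length and per 1e6 uniquely mapped reads, the total that the file headers give. The log2 fold change and log2 average expression columns, and the p-value and false discovery rate columns, are the authors' deposited edgeR values. The authors took genes with a p-value and a false discovery rate below 0.05, per the series' design text. The RPKM values were recomputed from the counts as a check of the units and were not used further.

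Everything else was computed from the counts. Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, which gave factors between 0.996 and 1.004. The log2 ratio of 2 libraries used a prior count of 2, scaled by library size. A gene was called measured with at least 50 reads in 1 of the 2 libraries. Its 95% interval is the exact conditional (Clopper-Pearson) interval of the ratio of the 2 counts. It covers counting error only, since reads are not independent molecules, and holds no variation between animals or cultures. With 1 library per group there is no spread between replicates, so no test of the conditions is reported as a result. The exact test of edgeR was run on these counts with assumed biological coefficients of variation of 0.01, 0.1 and 0.2, and with 0.01 for the treated column against the sum of both columns, only to compare its calls and p-values with the authors' deposited ones. Genes were counted by a rule of size, at least 2-fold higher or lower.

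The sets of genes were 42 lists fixed before the data were examined, as were the groups, the rule for named genes and the settings of the alternatives named first below. A list member was counted as higher or lower at 1.5-fold or more with an interval that excluded 0. The median log2 ratio of a list was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a test. The text describes the lists chosen for the study's subject, and those below the 2nd or above the 98th percentile or with at least 25% of measured members beyond 1.5-fold. The named genes are Nr3c1, the 10 highest and 10 lowest genes of each comparison by the interval bound nearest to 0, without predicted Gm and Rik symbols, and up to 4 members of each list with the log2 ratios farthest from 0. Some genes that this rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

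The functions were tested on simulated counts with 200 changed genes. In the hippocampus simulation, over 13333 measured genes, 12 of 25 genes raised 2-fold and 25 of 25 raised 3-fold passed the 2-fold rule, and 0 of 13133 unchanged genes did. In the HT22 simulation, over 10782 measured genes, the counts were 12 of 25, 25 of 25 and 0 of 10582. The intervals held the true ratio for 94.9% of the genes in the hippocampus simulation and 95.4% in the HT22 simulation. These simulations hold counting error only.

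Alternatives were total counts without TMM, DESeq2 1.42.0 size factors, prior counts of 0.25 and 10, minimums of 10 and 200 reads, and a rule that the whole interval lie beyond 2-fold. After the data were seen, a correction for coding length and GC content was added, which subtracts the median of genes in the same of 10 groups by length and of 5 groups by GC. GC was taken from the longest protein-coding transcript in GENCODE M21, whose identifiers matched 21939 of the 22328 genes, with a GC value for 21096. Also added was a count without genes at least 20 times higher in hippocampus than in HT22 cells. Python 3.11.15 and scipy 1.17.1 were used for the remaining steps.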

Results

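The series asks how choline supply before birth, or in culture, relates to gene expression in the hippocampus, with Nr3c1, the gene of the glucocorticoid receptor, named in its title. F1m-GCS offspring came from dams fed 5 g/kg choline chloride from embryonic day 9 until birth, and F1m-CON offspring from dams fed 1.1 g/kg. A behaviour test age of 2 months is recorded for the offspring of both groups. Whether each hippocampus library is 1 animal or a pool is not given in the sources used here. HT22 is an immortalised mouse hippocampal neuronal cell line. Choline chloride was given to its cultures at 5 µM in CON and at 70 µM in SUP, over 48 h. Reads counted in genes numbered 31175015 for F1m-CON, 30265820 for F1m-GCS, 18305096 for HT22 CON and 13192007 for HT22 SUP. They made up 79.4%, 79.0%, 72.9% and 63.1%, in the same order, of the uniquely mapped reads that the file headers give. Each group held 1 library, so no difference below has a replicate check. Values in brackets are 95% counting intervals of the log2 ratio, unless stated otherwise.

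Nr3c1 was higher in the hippocampus of F1m-GCS than of F1m-CON, with 3355 against 2883 reads and a log2 ratio of 0.27 (0.20 to 0.35). In the deposited table the gene (ENSMUSG00000024431) lies on chromosome 18 from 39410545 to 39491301 in mm10. In GENCODE M21 it starts at the same base and ends at 39519421. Its log2 ratio stood at percentile 90.6 of measured genes. In these 2 libraries genes with longer coding sequences had higher ratios, with medians from -0.09 in the shortest of 10 equal groups of genes to 0.11 in the longest. Ratios also fell with GC content, with a rank correlation across genes of -0.26. After a correction for coding length and GC content, chosen after the data were seen, the log2 ratio of Nr3c1 was 0.05 (-0.02 to 0.12). The authors' deposited table gives a log2 fold change of 0.27. Its calls equal those of an edgeR exact test with an assumed biological coefficient of variation of 0.01. No replicate libraries back that value, so the deposited false discovery rate of Nr3c1 is not used as evidence for a rise.

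Among 13392 measured genes in the hippocampus, 30 were at least 2-fold higher and 23 at least 2-fold lower in F1m-GCS. Tuba1c, an alpha-tubulin gene, had a log2 ratio of 1.78 (1.38 to 2.26), from 58 to 196 reads. Above 2-fold were also the zinc finger genes Zfp52 at 1.34 (0.93 to 1.82) and Zfp946 at 1.07 (0.80 to 1.36), the dynein gene Dnah12 at 1.59 (0.90 to 2.55) and Aqp9, a water and glycerol channel, at 1.45 (0.86 to 2.23). Ccdc129 had 1.30, Gprin3 1.26 and Postn, a matricellular protein, 1.18. Zfp40 at 0.96 and Arhgap5 at 0.81 completed the 10 highest. The lowest was Rpl19, a ribosomal protein gene, at -1.68 (-2.02 to -1.38), from 353 to 105 reads. Neurog2, a proneural transcription factor, had -1.57 (-2.37 to -0.97), and Hcrtr1, an orexin receptor, -1.52 (-2.27 to -0.94). Nrtn, a neurotrophic factor, had -1.47, Stoml3 -1.42, Lcn2 -1.31, Wdr65 -1.29, Spata33 -1.24 and Oca2 -1.15. Tuba1c and Rpl19 have near-identical copies in the genome, and the counting could split reads among them, so both values are uncertain. With the whole interval required to lie beyond 2-fold, 2 genes were higher and 1 was lower, and with at least 200 reads 3 were higher and 1 was lower.

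The marker set of the choroid plexus, the epithelium that makes cerebrospinal fluid, had the lowest median of the described lists. Of 19 measured members 18 had log2 ratios below 0 and 3 were lower by 1.5-fold, with a median of -0.41, below all 10000 random lists. Aqp1 had -0.79 (-1.02 to -0.58), Steap1 -0.72 (-1.07 to -0.39), Kcnj13 -0.71 (-0.99 to -0.44) and Clic6 -0.52 (-0.65 to -0.40). Ttr, named after its values were seen, had 52044 and 44039 reads and -0.19 (-0.21 to -0.17). Interferon response genes had a median of -0.22 at percentile 0.10, with 3 of 20 lower, among them Mx2 at -0.80, Psmb9 at -0.73 and Ifih1 at -0.62. Microglia markers had a median of -0.11 at percentile 0.79 and astrocyte markers -0.09 at percentile 0.10, with no member of either beyond 1.5-fold. C1qc had -0.27, while Aqp4 had 0.25. Ribosomal protein genes had a median of -0.14 and oxidative phosphorylation genes -0.12, both below all random lists, with 31 of 39 and 37 of 38 members below 0. These 2 medians were -0.07 and -0.07 after the correction for length and GC.

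The median log2 ratios of 3 lists of receptor genes lay above 0. GABA signalling genes had a median of 0.10 at percentile 99.9, with 16 of 20 above 0. Gabrb1 had 0.56 (0.44 to 0.68), Gabrb2 0.54 (0.46 to 0.62) and Gabra2 0.39 (0.28 to 0.50), while Gabrd had -0.26 (-0.39 to -0.13). Glutamate receptors and transporters had a median of 0.08 at percentile 99.7, with Grin2b at 0.41 (0.38 to 0.44), Grin2a at 0.40 and Slc17a6 at 0.39. Thalamus and habenula markers, a list that includes Slc17a6 and was singled out after its values were seen, had a median of 0.08 at percentile 92.9, with 11 of 14 above 0, or 0.16 over 9 genes at percentile 99.0 with at least 200 reads. Of the GABA and glutamate lists, 0 of 20 and 0 of 26 members reached 1.5-fold, and after the correction both lay inside the range of random lists, at percentiles 97.3 and 93.6. Monoamine and acetylcholine receptors had a median of 0.10 at percentile 99.4. Of 29 measured members 1, the dopamine receptor gene Drd2, was higher, with 66 against 43 reads and 0.65 (0.10 to 1.26). Extracellular matrix genes had a median of 0.13 at percentile 99.9, with Postn as the 1 higher member of 28. The 4 measured sex-linked genes, all on the Y chromosome, had a median of 0.29 at percentile 99.5, with Ddx3y at 0.69 (0.58 to 0.81). After the correction these 2 medians stood at percentiles 97.1 and 80.4.

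Among the lists on choline and methyl groups, one-carbon and methionine cycle genes had a median of -0.11 at percentile 0.15 in the hippocampus, with 21 of 26 below 0. Shmt2, a mitochondrial serine hydroxymethyltransferase, had -0.31 (-0.46 to -0.16) and Mthfd2l -0.44 (-0.78 to -0.10), while Aldh1l2 was higher at 0.60 (0.35 to 0.86). Choline and phosphatidylcholine metabolism genes had a median of 0.05 at percentile 93.0, or -0.00077 with at least 10 reads and percentile 98.6 with at least 200, with 1 of 27 higher, the butyrylcholinesterase gene Bche at 0.80 (0.54 to 1.08). DNA methylation genes had a median of 0.02, or -0.02 after the correction. Dnmt3b, a de novo methyltransferase, was the 1 lower member of 19, at -1.09 (-1.92 to -0.42) on 53 and 23 reads, while Tet1 had 0.50 and Tet2 0.49. Histone methylation enzymes had a median of 0.06 at percentile 98.1, with Setd2 at 0.43. The percentile was 97.6 with DESeq2 size factors, and the median was -0.01 after the correction.

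Genes that respond to glucocorticoids had a median of -0.08 at percentile 1.71, with Lcn2 as the 1 lower member of 23 and Plin4 at -0.48. The percentile was 2.92 with at least 200 reads and 24.8 after the correction. None of the 17 measured genes of the glucocorticoid receptor and stress axis was beyond 1.5-fold, and their median was -0.04, or 0.01 with at least 200 reads. Hsp90aa1, a chaperone of the receptor, had 0.28 (0.22 to 0.34), and Crh, the corticotropin-releasing hormone gene, had -0.40 (-0.97 to 0.14). Immediate early genes had a median of -0.01 and neurotrophins and growth factors -0.03, with no member beyond 1.5-fold. The medians of the other 23 lists lay between -0.07 and 0.11, at percentiles from 3.27 to 97.8. After the correction 5 of these lay outside the range of random lists, CA1, CA3, interneuron and endothelial markers above it and dentate gyrus markers below it.

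**Figure D1:**
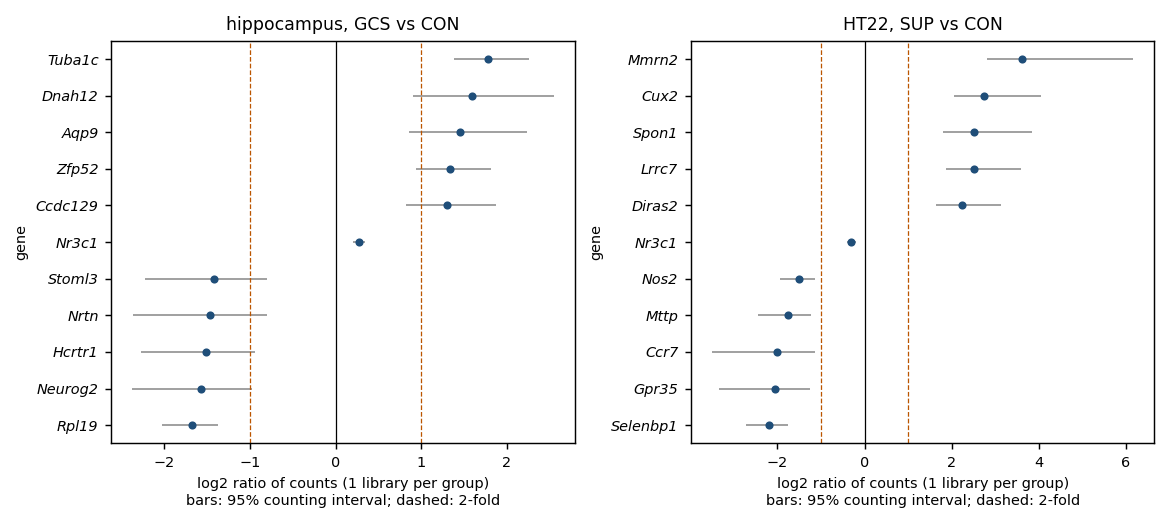
The log2 ratio (x axis) of Nr3c1 and of the 5 highest and 5 lowest genes, by the interval bound nearest to 0, in each comparison (y axis), with bars for the 95% counting interval and dashed lines at 2-fold. Nr3c1 lies at 0.27 in the hippocampus and at -0.30 in HT22 cells.

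In HT22 cells Nr3c1 was lower in SUP than in CON, with 1123 against 1939 reads and a log2 ratio of -0.30 (-0.41 to -0.20). It stood at percentile 15.1 of measured genes. Ratios in HT22 cells rose with GC content, with a rank correlation across genes of 0.17. After the correction for length and GC the log2 ratio of Nr3c1 was -0.19 (-0.30 to -0.09). The authors' deposited table gives a log2 fold change of -0.20, which is not the same contrast. The control level implied by that table weighted the CON and SUP counts by 49.9% and 50.1%.

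Among 10854 measured genes, 241 were at least 2-fold higher and 57 at least 2-fold lower in SUP. The highest was Mmrn2, an endothelial matrix gene, at 3.62 (2.80 to 6.17), from 4 to 54 reads. Next were Cux2, a transcription factor of upper cortical layers, at 2.74 (2.04 to 4.05), Lrrc7 at 2.51 (1.87 to 3.60), Spon1 at 2.52, Diras2 at 2.24, Syne1 at 2.12, Celf3 at 2.06, Akap5 at 2.05 and Cplx1, a regulator of synaptic vesicle release, at 2.03. Alas2, the haem synthesis enzyme of red cells, had 2.00 (1.56 to 2.59). The lowest was Selenbp1 at -2.19 (-2.73 to -1.77), from 283 to 43 reads. Gpr35 had -2.04, Ccr7 -2.01, Susd1 -1.75, Mttp -1.75, Thnsl1 -1.47, Ces1g -1.36 and Serpina3m -1.34. Nos2, the inducible nitric oxide synthase, had -1.51 (-1.94 to -1.14) and the cytokine gene Il33 -1.29 (-1.75 to -0.89). With the whole interval beyond 2-fold, 112 genes were higher and 7 lower. With at least 200 reads the counts were 68 and 7.

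Most of the genes that were 2-fold higher in SUP were genes of high level in the hippocampus and low level in HT22 cells. Of the 241, 162 were at least 20 times higher in the hippocampus libraries than in the HT22 libraries, a class that held 297 of the 10854 measured genes. Without that class, 79 genes were higher and 55 lower. Genes at least 100 times higher in hippocampus had a median log2 ratio of 1.26, and genes 1 to 2 times higher had -0.09. With a mean of at least 50 reads in the 2 HT22 libraries these medians were 1.21 and -0.08. Over 643 such genes with a CPM (counts per 1e6 reads in genes) of at least 50 in hippocampus and under 1/100 of that in HT22, the pooled level was 0.335% of the hippocampus level in CON and 0.804% in SUP.

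Pan-neuronal genes had a median of 1.26, above all random lists, with 10 of 15 higher and 1 lower. Uchl1 had 1.90 (1.41 to 2.54), Nefl 1.76 (1.09 to 2.73), Stmn2 1.61 (1.05 to 2.34) and Camk2a 1.43 (1.27 to 1.60). Glutamate receptors and transporters had a median of 1.13, also above all random lists, with 6 of 10 higher, among them Grin2b at 1.52 (1.29 to 1.77), Gria3 at 1.35, Gria1 at 1.31 and Slc17a7 at 1.28. GABA signalling genes had a median of 1.00 at percentile 98.2, with 3 of 4 higher, among them Gabbr2 at 1.25, and the percentile was 97.9 with DESeq2 size factors. Without genes at least 20 times higher in hippocampus, the medians of the pan-neuronal and glutamate lists were -0.16 over 5 genes and 0.02 over 4 genes. With at least 200 reads they were 0.70 over 10 genes and 0.32 over 5 genes. Markers of other brain cells went both ways. Astrocyte markers had a median of 0.22 at percentile 98.6, with 3 of 7 higher, among them Slc1a2 at 1.27, and 3 of 7 below 0, among them Slc1a3 at -0.26. Oligodendrocyte markers had 0.41 at percentile 99.1, with 2 of 5 higher, among them Mbp at 0.97. With at least 200 reads these 2 lists stood at percentiles 90.1 and 68.4, and oligodendrocyte markers at 91.8 after the correction. With at least 10 reads their medians were 1.27 over 15 genes and 0.93 over 9 genes, at percentiles 100 and 99.6. The 4 measured microglia markers were all below 0, with a median of -0.20, while 11 others, each at least 20 times higher in hippocampus and under 50 reads, had 29 reads in all in CON and 65 in SUP. Without the same class the medians were -0.06 for astrocyte and 0.03 for oligodendrocyte markers, at percentiles 44.4 and 70.6. Neocortex markers had a median of 0.52 at percentile 99.4, led by Cux2, and stood at percentile 91.4 with at least 10 reads. Of 3 dentate gyrus markers 1 was higher, Pdzd2 at 1.66, with a median of 0.43, or 1.46 over 6 genes with at least 10 reads. Of 3 interneuron markers 1 was higher, Cck at 0.79, and 2 lay below 0, with a median of -0.02. Of 5 CA1 markers 2 were higher, among them Zbtb20 at 0.69, and 1 was lower, Dcn at -0.63, with a median of -0.13. With at least 10 reads the interneuron and CA1 medians were 0.73 and 0.59, and after the correction the interneuron median was 0.0064. Htr2c was the 1 measured monoamine receptor gene, at 1.30, and Alas2 the 1 measured blood marker.

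**Figure D2:**
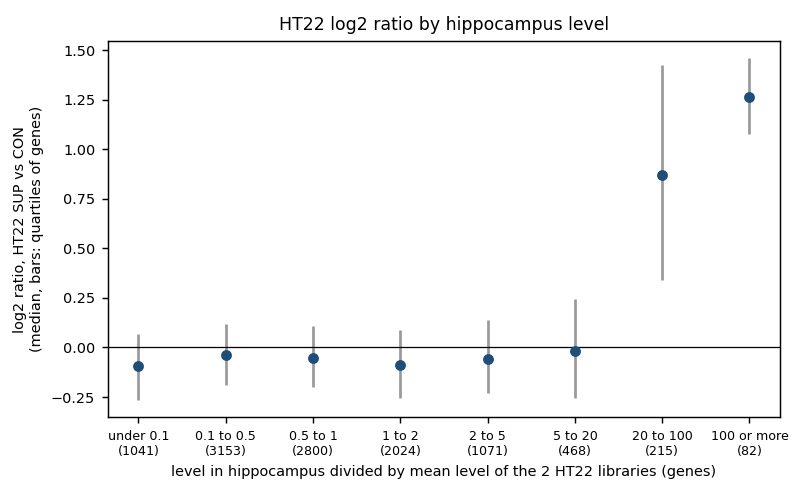
The log2 ratio of HT22 SUP against CON (y axis; points are medians and bars quartiles over genes) by the level of the gene in hippocampus divided by its mean level in the 2 HT22 libraries (x axis, with the number of genes). Medians lie at or below 0 in all classes under 20 and at 0.87 and 1.26 in the upper 2.

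All 18 measured p53 targets had log2 ratios below 0 and 3 were lower by 1.5-fold, with a median of -0.37 below all random lists. Eda2r had -0.87 (-1.16 to -0.60), Trp53inp1 -0.83 (-0.97 to -0.69), Cdkn1a, a cell cycle inhibitor, -0.80 (-0.89 to -0.73) and Sesn1 -0.56 (-0.74 to -0.38). Inflammation genes had a median of -0.30, also below all random lists, with 5 of 18 lower. Besides Nos2 and Il33, the interleukin gene Il1b had -1.33 (-2.11 to -0.73) and the chemokine gene Cxcl10 -1.18 (-1.85 to -0.63). Interferon response genes had a median of -0.33 at percentile 0.31, with 4 of 14 lower, among them Gbp3 at -1.45, Psmb9 at -1.02 and Gbp2 at -0.73. With at least 200 reads, 9 of these were measured and the percentile was 28.2. Hypoxia and glycolysis genes had a median of -0.28, below all random lists, with 4 of 21 lower, namely Ankrd37 at -0.74, Pdk1 at -0.72, Ndrg1 at -0.72 and Adm at -0.69. Genes that respond to glucocorticoids had a median of -0.30, below all random lists, with Cdkn1a, Ddit4 at -0.71 and Dusp1 at -0.63 as the 3 lower members of 19. After the correction for length and GC the median of the glucocorticoid-responsive list was -0.19 at percentile 0.03. Cdkn1a stands in this list and in that of p53 targets.

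Extracellular matrix genes had a median of -0.15 at percentile 0.38, with 0 of 28 beyond 1.5-fold, and cell cycle genes -0.12 at percentile 1.48, with 2 of 30 higher and 0 lower. Choroid plexus markers had a median of -0.37 with 2 of 6 lower, and endothelial markers -0.27 with 0 of 4 beyond 1.5-fold. Meningeal and fibroblast markers had a median of -0.21 at percentile 2.53, with 8 of 9 below 0, Dcn and Igf2 lower, and Ptgds higher at 1.74. That list lay below the 2nd percentile with at least 10 reads, with at least 200 reads and after the correction, where its median was -0.41. After the correction cell cycle genes stood at percentile 5.35. Choroid plexus markers stood at percentile 6.66 with at least 200 reads, and the endothelial median was 0.06 with at least 10 reads. Among cell cycle genes Cenpe was higher at 0.99 (0.93 to 1.04) and Mki67 at 0.60 (0.56 to 0.63), while Pcna had -0.39. Histone methylation enzymes had a median of 0.21, above all random lists, with 5 of 30 higher. Kmt2d had 1.29 (1.22 to 1.36), Kmt2a 0.94 (0.86 to 1.02), Kmt2c 0.92 (0.79 to 1.05) and Nsd1 0.90 (0.60 to 1.21). These genes have long coding sequences. The longest of the 10 groups of measured genes had a median of 0.29, against -0.12 to 0.02 in the other 9, and after the correction the median of the list was 0.04 at percentile 83.1. Ribosomal protein and oxidative phosphorylation genes both had a median of 0.13 above the 98th percentile, with Atp5g1 at 0.57. Rps7 at 1.23 and Rpl19 at -0.82, each with near-identical copies in the genome, are uncertain.

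Of the lists on choline and methyl groups, all but histone methylation enzymes lay within the range of random lists in HT22 cells. Choline and phosphatidylcholine metabolism genes had a median of -0.08, or 0.01 after the correction, with 0 of 22 beyond 1.5-fold. The choline transporter-like genes Slc44a2 and Slc44a1 had -0.36 (-0.45 to -0.28) and -0.27 (-0.37 to -0.18). One-carbon and methionine cycle genes had a median of -0.05, or 0.04 after the correction, with Mtr, the methionine synthase, higher at 0.77 (0.59 to 0.95) and Mthfd2l lower at -0.72 (-1.01 to -0.45). DNA methylation genes had a median of 0.05, with Dnmt3b as the 1 higher member of 20 at 0.70 (0.25 to 1.18), and Tet2 at 0.52. The 11 measured genes of the glucocorticoid receptor and stress axis had a median of 0.03, none beyond 1.5-fold, with Hsp90aa1 at 0.37 and Hsd11b1 at -0.31. Immediate early genes had a median of -0.17, with Npas4 lower at -0.64, Inhba higher at 0.62 and Jun at -0.58. Neurotrophins and growth factors had a median of -0.10, or 0.0083 with at least 10 reads, with Ntrk2 at 1.42 and Igf1r at 0.73 higher and Igf2 at -0.82 lower. The medians of the other 9 lists with at least 3 measured members lay between -0.20 and 0.14, at percentiles from 4.45 to 91.9.

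**Figure D3:**
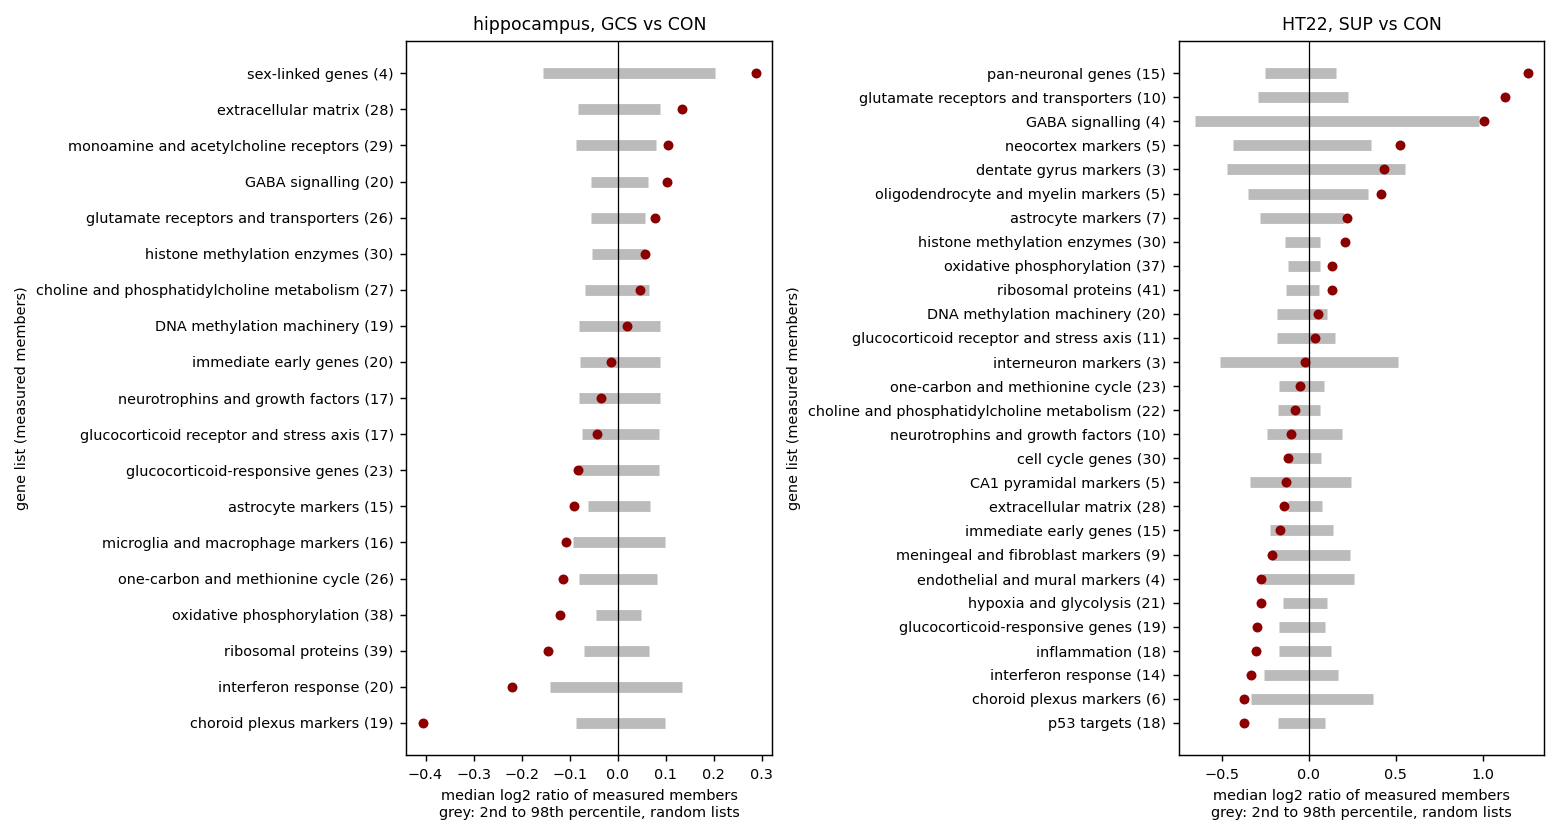
The median log2 ratio (x axis, red points) of the described gene lists (y axis, with the number of measured members), in the hippocampus and in HT22 cells, over grey bars from the 2nd to the 98th percentile of matched random lists. Choroid plexus markers lie at -0.41 in the hippocampus, and pan-neuronal genes at 1.26 and p53 targets at -0.37 in HT22 cells.

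The 2 comparisons share no library. Across 10234 genes measured in both, the log2 ratios had a Spearman correlation of 0.157 and a Pearson correlation of 0.168. Genes are not independent replicates, so no p-value is given. By the 2-fold rule 1 gene, Hist2h4, was higher in both, against 0.352 for independent lists, and 1 gene, Trim30d, was lower in both, against 0.0274. These 2 were named after their values were seen. By a 1.5-fold rule 21 were higher in both, against 6.90, and 8 were lower in both, against 1.13.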

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

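None of the comparisons in this part was planned before the data were examined, and with 1 library per group no difference between the tissue and the cell line was tested. Each item had log2 ratios of opposite sign in the hippocampus and in HT22 cells. For Nr3c1 the log2 ratio was 0.27 in the hippocampus and -0.30 in HT22 cells, a difference of -0.58, and the hippocampus value was 0.051 (-0.021 to 0.123) after the correction for length and GC. Dnmt3b had -1.09 in the hippocampus and 0.70 in HT22 cells, a difference of 1.78, on 53 and 23 reads in the hippocampus and 75 and 88 in HT22 cells. Among gene lists outside the range of random lists in both comparisons, the medians of ribosomal protein genes differed by 0.28 (-0.14 and 0.13), those of oxidative phosphorylation genes by 0.25 (-0.12 and 0.13) and those of astrocyte markers by 0.31 (-0.09 and 0.22). After the correction the hippocampus medians of ribosomal protein and oxidative phosphorylation genes were closer to 0, at -0.071 and -0.065. Without genes 20 times higher in hippocampus the astrocyte median in HT22 cells was -0.063, the same sign as in the hippocampus. For extracellular matrix genes the difference was -0.28 (0.13 and -0.15), and the hippocampus list stood at percentile 97.1 after the correction.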

How the results depend on the processing

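With 1 library per group, leaving out a replicate and permuting the labels could not be done, and no paired analysis was possible because each group has a single library. Scaling moved little. Counts at 2-fold stayed within 1.5 times under total counts, DESeq2 size factors, a prior of 0.25 and, added after the data were seen, the correction for length and GC. The minimum of reads set the counts. At least 10 reads gave 194 higher and 150 lower genes in the hippocampus and 818 and 167 in HT22 cells, and at least 200 reads gave 3 and 1, and 68 and 7. A prior of 10 gave 16 and 13 in the hippocampus and 30 lower genes in HT22 cells. With the whole interval beyond 2-fold the counts were 2 and 1, and 112 and 7. Without genes 20 times higher in hippocampus 79 genes were higher in HT22 cells, and 68 where this class was set by the HT22 CON level alone, the first split tried. The log2 ratio of Nr3c1 was 0.26 and 0.27 in the hippocampus and -0.31 and -0.30 in HT22 cells under total counts and DESeq2 size factors, and the correction gave 0.051 in the hippocampus and -0.19 in HT22 cells. The Spearman correlation of the comparisons was 0.167 with at least 200 reads and 0.129 after the correction. By a 1.5-fold rule the shared genes were 21 higher and 8 lower. The cause was not tested, apart from the genes that each minimum adds or removes.

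Among described lists outside the range of random lists, medians changed sign in 4 cases: histone methylation enzymes in the hippocampus at -0.0083 after the correction, and in HT22 cells endothelial markers at 0.061 with at least 10 reads, and pan-neuronal genes at -0.16 and astrocyte markers at -0.063 without genes 20 times higher in hippocampus. Described lists inside that range changed sign in 9 further cases over 8 lists, which are given with those lists. Of the 14 hippocampus lists outside the range of random lists, 13 stayed outside under each other scaling and 8 after the correction, which put 5 other lists outside. Of the 18 in HT22 cells, 17 stayed outside under each other scaling and 14 after the correction, which put 1 other list outside. The HT22 SUP library has the fewest reads in genes, 13192007, and its genes near 50 reads carry the widest intervals.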

Other observations

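The tests in this part were chosen after the data were seen. In HT22 SUP, of 20 measured Hist genes 19 had log2 ratios above 0, with a median of 0.61 at percentile 99.9 of random lists, and 7 were at least 2-fold higher, among them Hist1h1d, named after its values were seen, at 1.85 with 34 and 92 reads. The median was 0.55 after the correction for length and GC and between 0.60 and 0.62 under other scalings. Most histone mRNAs lack a poly(A) tail and many are near-identical copies, so their counts after poly(A) selection are uncertain. In the hippocampus 10 measured Hist genes had a median of -0.04, or 0.057 after the correction. Of zinc finger genes named Zfp, 231 of 316 were, in the hippocampus, above 0, with a median of 0.12 at percentile 100, or 0.07 after the correction, and in HT22 cells 183 of 280 were below 0, with a median of -0.11 at percentile 2.3, inside the range of random lists, or -0.02 after the correction. The median of all measured HT22 genes was -0.05 before the correction.

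The 79 genes that were 2-fold higher in HT22 SUP and not 20 times higher in hippocampus had a median coding length of 2832 bases, against 1401 for all measured genes. Among them, named after their values were seen, were Ahnak at 1.44, Dst at 1.40 and Plec at 1.15. Lars2, named likewise, had 1.23 and a coding length of 2709 bases, below the median of the 79.

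Of 297 measured brain-enriched genes 270 had log2 ratios above 0 in HT22 SUP. Genes of low level could count as measured through their SUP reads alone, which raises this share. With a mean of at least 50 reads in the 2 HT22 libraries, 188 genes 20 to 100 times higher in hippocampus had a median of 0.72. For 54 genes at least 100 times higher it was 1.21. RNA or reads of the study's own hippocampus libraries, as the whole cause, would raise all genes in proportion to their hippocampus level. However, the median excess of myelin markers, as a share of that level, was 0.213 of that of pan-neuronal genes (bootstrap 95% interval -0.16 to 0.37). Median shares were 0.163% for myelin and 0 for choroid plexus markers, against 0.764% for pan-neuronal genes, 0.224% for neocortex and 0.417% for dentate gyrus. They were 0.701% for astrocyte and 0.900% for microglia markers. The 2 blood markers had 0.888%, from Hbb-bs (2 and 7 reads) and Car2 (3 and 15), named after their values were seen. These shares bear on hippocampus RNA as the whole cause only, and a part of the rise from it stays open. Genomic DNA would raise silent genes, and the pooled log2 ratio of 1404 olfactory and vomeronasal receptor genes was -0.037 (-0.26 to 0.18). A neuronal programme of the cells as the whole cause would leave non-neuronal brain transcripts in place. However, 47 of these, from myelin, choroid plexus, blood and microglia, had a pooled log2 ratio of 0.74 (0.58 to 0.92). The pooled ratio was 1.09 (0.85 to 1.36) for 16 myelin genes. It was 2.27 for 6 blood genes (10 reads in CON and 41 in SUP) and 1.57 for 11 microglia genes (29 and 65). For 14 choroid plexus genes it was -0.018 (-0.30 to 0.26), on 262 and 185 reads. Most of those reads were of Igf2 (56 and 22) and Enpp2 (172 and 110, named after its values were seen). Without Igf2 and Enpp2 the other 12 had 1.07 (0.48 to 1.79) on 34 and 53 reads, of which Ttr had 5 and 29. RNA from other neural cells or tissue may account for part of the pattern but was not tested, and an effect of choline on the cells stays open and untested.

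Log2 ratios went with coding length, with a rank correlation across genes of 0.349 in the hippocampus and 0.216 in HT22 cells. In HT22 cells medians by length were not a steady rise: of 10 groups the shortest had -0.0024, the fourth -0.12, the ninth 0.02 and the longest 0.29. With GC content the rank correlations were of opposite sign, -0.255 in the hippocampus and 0.166 in HT22 cells. GC content as the whole cause is argued against, since the correlations were 0.385 (0.370 to 0.400) and 0.218 (0.20 to 0.24) once GC was removed. Brain-type reads in HT22 cells stay open as a cause. Among genes no higher in hippocampus than in HT22 cells the correlation was 0.142 (0.116 to 0.164), above the bound of 0.108 set for the test, but it was 0.120 (0.0962 to 0.145) with the split by HT22 CON alone. A difference in RNA or library quality cannot be told apart from the treatments with 1 library per group, and the smaller correlation, 0.216, is the pattern itself and bears on neither.

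In the hippocampus 18 of 19 choroid plexus markers had log2 ratios below 0. The length and GC trend is argued against, since the corrected median was -0.36, below all matched random lists. Less choroid plexus tissue in the F1m-GCS sample cannot be told apart from an effect of the diet with 1 sample per group, and the 94.7% of markers below 0 is the pattern itself and bears on neither. The markers were not lower alike, with Ttr at -0.19 (-0.21 to -0.17) and Aqp1 at -0.79 (-1.02 to -0.58), intervals that cover counting error only.

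The deposited fold changes of the 2 tables relate to the counts in different ways. In the hippocampus table the authors' deposited calls at a false discovery rate of 0.05, 3176 genes, equal those of an edgeR exact test with an assumed biological coefficient of variation of 0.01. The same test with 0.1 called 11 genes and with 0.2 called 1. In the HT22 table the authors' deposited fold changes had a slope of 0.557 against those of the count columns over 8681 genes with at least 200 reads in each library, and the sign differed for 6.30% of them. The control level implied by that table weighted the CON and SUP counts by 49.9% and 50.1%. A test of SUP against the sum of both columns gave a slope of 0.990 and 2226 calls, against 2132 deposited calls, and 11 genes with 0 reads in both libraries had a fold change other than 0. All HT22 values in the report come from the count columns unless the authors' deposited table is named.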
